A study of Homo sapiens with 6 samples.

How the data were processed

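Chemerin-binding and nonbinding CD8 EMRA T cells were sorted from blood mononuclear cells of 3 donors, per the labels' protocols, and 6 libraries were made from full-length cDNA with a low-input amplification kit and transposase-based tagging. The kit does not mark strand, and whether the counting used strand is not given in the sources used here, so overlapping antisense genes cannot be separated. Per the submitters' processing notes, bcl2fastq 2.17, Trimmomatic 0.36, STAR 2.5.2b, featureCounts, Subread 1.5.2 and DESeq2 were named with the build GRCh38.p13; their settings and gene annotation are not given in the sources used here. The authors deposited a signal per gene and library, namely normalized counts: each library's read counts divided by 1 size factor. A second table repeats these values, with a largest difference of 0, and adds the authors' deposited log2 fold changes and the authors' deposited p-values and adjusted p-values. In it a positive log2 fold change means higher in nonbinders: 98.9% of these values equal the log2 ratio of the group means, nonbinder over binder, within 0.01. It gives no adjusted p for 104 genes, and its test design is not given in the sources used here. Fold changes equal to plain ratios of group means point to a test without a donor term. All 6 columns of libraries were used.

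Every value was a whole multiple of a single step in its library (100% of values within 0.01 of a read), which gave the depth: totals of 45120689 to 52428780 reads. The steps were used to describe depth, reads behind a value and floors, and no count test was run. Floors (3 reads per library) and 95% intervals of ratios cover counting error only, since the amplified reads carry no molecular identifiers. No libraries were identical, and the correlations within a group ran from 0.891 to 0.940. Of the gene identifiers, 99.6% matched GENCODE 29 on GRCh38, which supplied coordinates; 52 rows had no symbol and 9 symbols occurred more than once.

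Groups and replicate numbers came from the sample titles. The test was limma 3.58.1 in R 4.3.3 (linear model with a mean-variance trend) on log2(normalized count + 1), for the 17568 genes with a mean of at least 10; the filter left out 60. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. The model held the 2 groups and no donor term, and a fit with the donor as a block was also fixed beforehand. The libraries of a replicate number come from the same donor as far as the protocol, the labels and the values tell. Their deposited names share a letter within each number (A, C or D). Deviations from the group means correlated at 0.348, 0.294 and 0.289 between libraries of the same number. Each library correlated best with its own number (highest value for other numbers −0.0598). Such deviations cancel within a group, so positive values for the same number lower the others, and this contrast is partly built in. The blocked adjusted p is printed for some of the genes whose call the block changes. An SE is from the fit without the block unless stated.

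On data simulated from these libraries (16756 genes), only genes with a mean normalized count of at least 100 were changed. Noise between libraries was drawn from normal distributions with the fitted variances. There the test without the block recovered 13.4%, 77.6% and 98.5% of genes changed by 1, 2 and 4 on the log2 scale, with 3 false calls among 129. With the block it recovered 61.2%, 95.5% and 100%, with 18 false calls among 189. These shares hold for the simulation only. In the real libraries CCR4 (log2 difference −8.37) and CMKLR1 (5.72) did not pass without the block. In limma with the block CCR4 passed (adjusted p = 0.0189) and CMKLR1 still did not (adjusted p = 0.0849).

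In all, 24 gene lists were fixed before the data were examined, as were the test, its alternatives and the rule for named genes. The 23 lists with at least 3 measured members were tested with camera (preset correlation 0.01, and an estimated correlation) and fry. Counts adjusted over the list alone are without the block unless stated, and the blocked count is given where it differs by over 1.5 times. Camera called 6 lists higher and 5 lower, 7 and 5 with the block, and 0 with an estimated correlation (smallest adjusted p = 0.165). Fry asks whether a list's genes move on balance 1 way. It called 4 lists without the block. These were naive and memory genes and effector-lineage transcription factors (adjusted p = 0.0129 each), and cytotoxic effectors and MAIT cell markers (adjusted p = 0.0452 each). Only the naive and memory genes passed fry with the block (adjusted p = 0.0403). No other list passed fry in either fit. The median log2 difference over all genes was −0.00112, so fold changes needed no recentring. The named genes were the chemerin receptors, then in each direction the 15 largest changes among genes past the threshold with the same direction in 3 pairs, first without the block and then filled with calls from the fit with the block, and up to 4 members of each list by smallest p. Variable receptor segments, sex-linked XIST and Y genes, pseudogenes and genes with only identifier names were left out of the first 2 parts. Genes named outside this rule, namely CCR7, FCGR3A, CD244, LILRB1, GZMH, TRAC, SH2D1B and the genes that no list holds, were chosen after their values were seen. A gene that the rule selects is not reported here. Alternatives were other pseudocounts, filters, scalings, sample weights, a robust variance prior and leaving out each library and each pair; the same settings with the block were chosen after seeing the data.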

Results

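Gene expression was measured by RNA sequencing of very small cell numbers in human blood CD8 T cells of the EMRA type, effector memory cells that had been gated as CD8-positive, CD45RO-negative and CCR7-negative. The cells were sorted by flow cytometry into those that bound chemerin, a chemoattractant protein, and those that did not. Each of 3 donors gave 1 binder and 1 nonbinder library, so that 6 libraries formed 3 donor pairs. The libraries held between 45120689 and 52428780 reads assigned to genes, read back from the spacing of the normalized counts. The table listed 17628 genes, of which between 16901 and 17420 were above 0 in a library. Levels are normalized counts, given as mean ± SD with n = 3 libraries per group, and fold changes are on the log2(normalized count + 1) scale, binder over nonbinder. Positions are on GRCh38.

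The comparison asked how the transcriptome of chemerin-binding EMRA cells differs from that of their nonbinding counterparts, and which chemerin receptor they express. CMKLR1, the main signalling receptor for chemerin (ENSG00000174600, chromosome 12, 108288044 to 108339341, minus strand), was at 373 ± 23.2 normalized counts in binders and 16.7 ± 23.0 in nonbinders. The binder libraries lay between 350 and 396 and the nonbinder libraries between 0 and 43.0, and the level was higher in binders in 3 of 3 pairs. The log2 difference was 5.72 (SE 1.22). It did not pass over all genes with limma (adjusted p = 0.169, or 0.0849 with the donor as a block), and it passed when adjusted over the list alone (adjusted p = 0.00370), a list of 3 chemerin receptors of which 2 were tested. CCRL2, a chemerin-binding receptor without known signalling, was at 373 ± 317 in binders and 452 ± 194 in nonbinders (log2 difference −0.48, SE 0.62; adjusted p = 0.883). GPR1, the remaining receptor of the list, was not analysed here. A nonbinder library at 0 reads allowed up to 3.02 normalized counts of CMKLR1 at its depth.

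The lists of naive and memory genes and of MAIT cell markers were lower in binders, and those of cytotoxic effectors and NK cell genes higher, at a preset correlation between genes; each of these lists had an adjusted p = 0.165 with an estimated correlation. Without a donor term, 3 genes fell and none rose. CD28, the costimulatory receptor lost during late differentiation, fell from 13724 ± 4458 to 732 ± 150 normalized counts, which was 18.2-fold lower. LTB, the membrane subunit lymphotoxin beta, fell 14.9-fold from 4501 ± 1605 to 291 ± 44.5, and RCAN3, a regulator of calcineurin, fell 56.8-fold from 3119 ± 1375 to 52.5 ± 17.0. Each of the 3 was lower in 3 of 3 pairs with an adjusted p of 0.0103 in limma. CD28 lies on chromosome 2 (203706475 to 203738912, plus strand), LTB on chromosome 6 (31580525 to 31582522, minus strand) and RCAN3 on chromosome 1 (24502351 to 24541040, plus strand). With the donor as a block, 63 genes rose and 119 fell in binders, the 3 above among them. At an unadjusted p under 0.05 without the block, 671 genes were higher and 885 lower. No gene passed without the block when any whole pair, or either library of pair 3, was left out, and none passed with the block when pair 1 or pair 2 was left out.

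Among the genes that fell with the donor as a block, CCR4 had the largest fitted change on the log2(normalized count + 1) scale. For genes with few or no binder reads, this ranking depends on the added 1. CCR4, a receptor of skin-homing and helper T cells, was at 1287 ± 891 in nonbinders and 5.85 ± 9.23 in binders, a log2 difference of −8.37 (SE 1.07; adjusted p = 0.0623, or 0.0189 with the block). CCR6, the receptor for CCL20, was at 570 ± 358 against 1.37 ± 1.19, with 4 reads over the 3 binder libraries. Its log2 difference was −7.79, with SE 0.81 and limma adjusted p = 0.0516 without the block, and SE 0.79 and adjusted p = 0.0319 with it. CCR8 had no read in the binders and was at least 48.7-fold lower, counted against a floor of 3 reads per library. The same bound was at least 106-fold for LRRN3, a leucine-rich repeat protein of naive T cells, 86.0-fold for KIT, the stem cell factor receptor, 73.6-fold for CAV1, the caveolar coat protein, 52.3-fold for CR1, a complement receptor, and 38.3-fold for ME1, the cytosolic malic enzyme. MAL, a membrane protein of T cells, had 1409 reads in nonbinders and 3 in binders, and the ratio of levels was 480 (95% interval 164 to 2330). FXYD2 (log2 difference −7.04) and FAAH2 (log2 difference −7.00) were also among the largest falls. Each of these genes was lower in 3 of 3 pairs, which the rule for named genes required.

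Among the genes that rose with the donor as a block, several encode receptors, chemokines and granule proteins of cytotoxic lymphocytes. CX3CR1, the fractalkine receptor of effector T and NK cells, rose 6.83-fold from 1792 ± 134 to 13378 ± 7297 normalized counts (log2 difference 2.77, SE 0.34; adjusted p = 0.0623, or 0.0287 with the block). CXCR2, a receptor for CXCL8, rose from 17.1 ± 12.5 to 625 ± 324. Its log2 difference was 5.41, with SE 0.48 and adjusted p = 0.0249 in limma with the block. GZMB, the serine protease granzyme B, rose 5.85-fold from 13020 ± 4705 to 74002 ± 17933. FASLG, a death ligand, rose 5.26-fold from 1577 ± 973 to 8664 ± 6310, and FGFBP2, a secreted protein of cytotoxic lymphocytes, rose 7.06-fold from 2468 ± 2617 to 13178 ± 6538. The chemokine genes CCL3 and CCL4 rose 5.37-fold and 6.19-fold. CCL4L2 rose 5.88-fold, although reads of CCL4 and its near-identical copy CCL4L2, and of CCL3 and its copies, cannot be assigned with certainty. The serine protease gene PRSS23 rose 5.33-fold. DGKK (log2 difference 6.05), SLC1A7 (3.40), PALLD (3.36), NME8 (2.96), RASSF4 (2.65) and MLC1 (2.61) were the others among the 15 named genes that rose. All 15 were higher in 3 of 3 pairs, which the rule for named genes required. CX3CR1 lies on chromosome 3 (39263494 to 39281735, minus strand), GZMB on chromosome 14 (24630954 to 24634267, minus strand) and CXCR2 on chromosome 2 (218125289 to 218137253, plus strand).

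**Figure D1:**
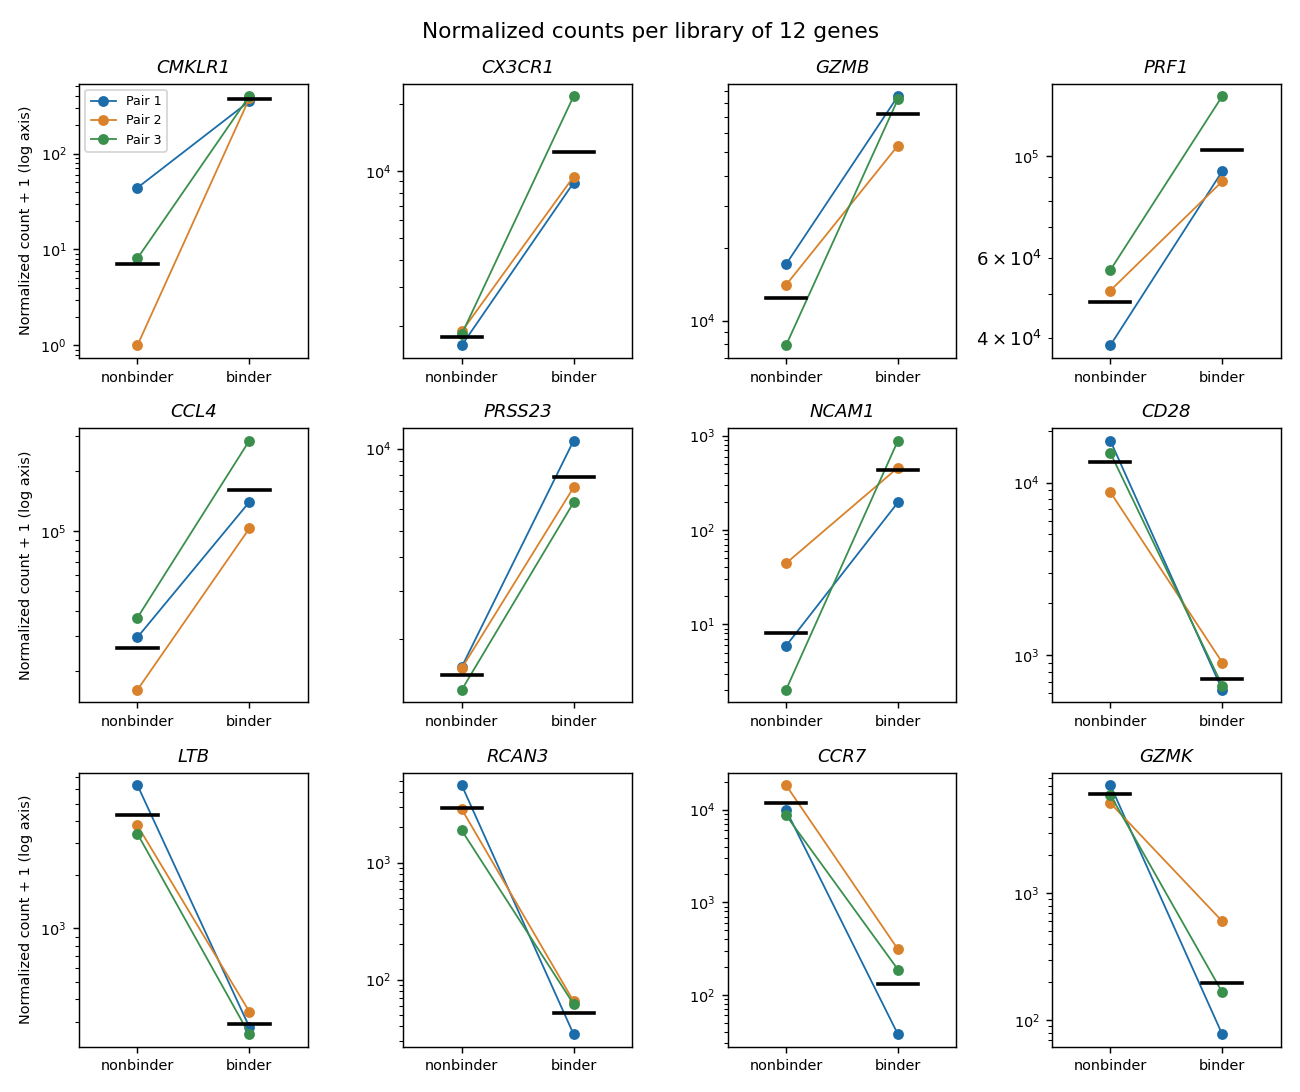
Normalized counts plus 1 (log axis) of 12 genes in the nonbinder and binder library of each of 3 donor pairs; lines join the libraries of a pair and black bars are group means on the log2 scale. CMKLR1 lies between 350 and 396 in the binder libraries and between 0 and 43.0 in the nonbinder libraries, and CD28, LTB and RCAN3 are lower in binders in 3 of 3 pairs.

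**Figure D2:**
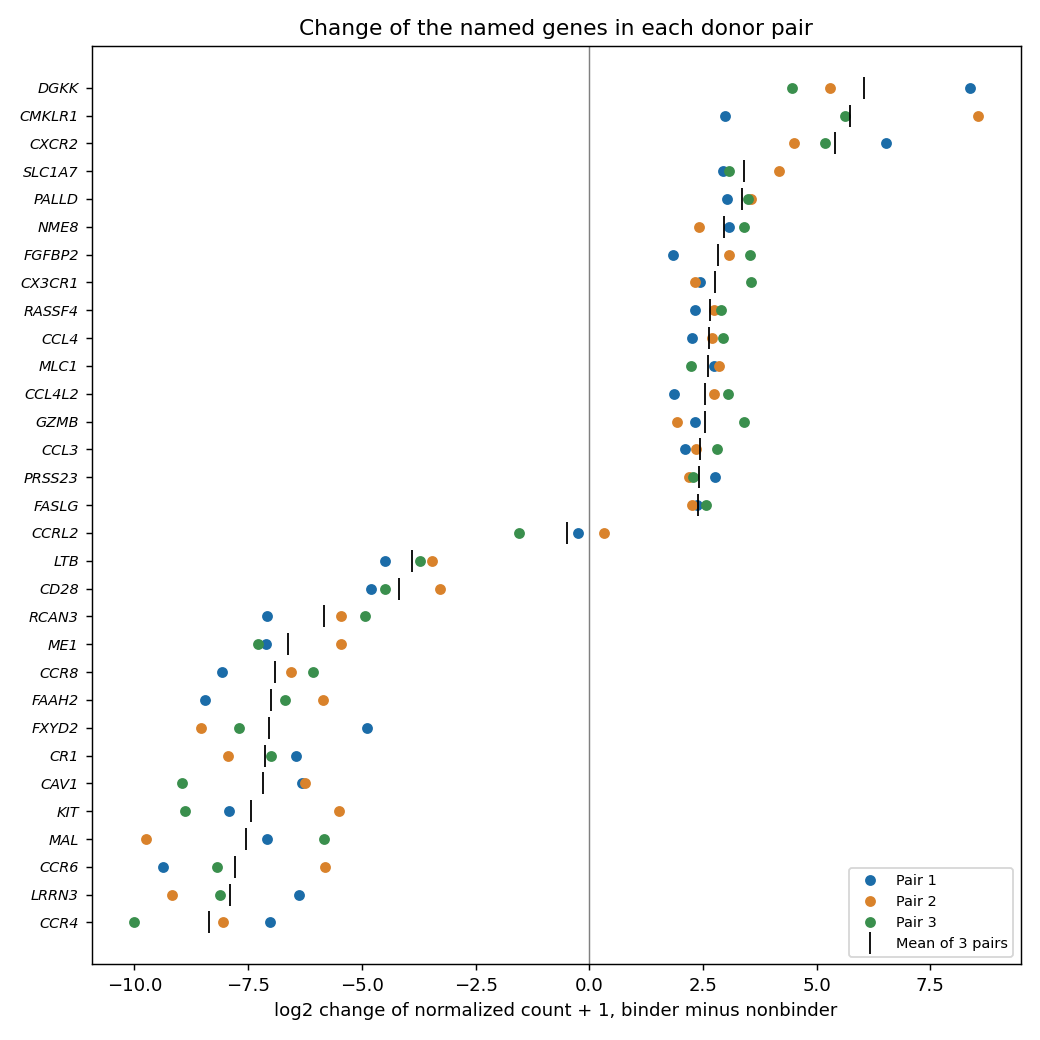
Change of the named genes in each of 3 donor pairs (points) and the mean over pairs (bars), as the log2 difference of normalized count plus 1, binder minus nonbinder. CCRL2 is on both sides of 0; for genes with no binder reads, such as LRRN3, the plotted size depends on the added 1.

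The naive and memory list fell as a group. Of its 21 measured members, 14 fell and none rose with the donor as a block over all genes, 2 fell without the block (CD28 and LTB), and 17 fell when adjusted over the list alone. BACH2, a repressor of effector differentiation, fell 7.50-fold, from 2504 ± 847 to 326 ± 73.9. Its log2 difference was −2.91, with SE 0.17 and adjusted p = 0.0185 in limma with the block. The median log2 difference was −2.28, and the medians of the 3 pairs were −2.74, −2.95 and −2.85. CCR7, the lymph node homing receptor, is among the 14, at 178 ± 137 in binders and 12342 ± 5291 in nonbinders, although both groups had been gated as negative for its protein. The list passed limma's camera test at a preset correlation (adjusted p = 4.00e-22), with an adjusted p = 0.165 with an estimated correlation.

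The MAIT cell list, markers of mucosal-associated invariant T cells, also fell. With the block, 4 of 13 measured members fell and none rose, CCR6, ME1 and CXCR6 among them, and 8 fell when adjusted over the list alone (9 fell and 1 rose so with the block). CXCR6, a tissue-homing chemokine receptor, fell 10.5-fold with the block, from 5242 ± 4981 to 415 ± 316 (adjusted p = 0.0348). The median log2 difference was −3.39, with pair medians of −3.94, −0.52 and −3.79. The camera test gave an adjusted p = 9.81e-08, with an adjusted p = 0.165 with an estimated correlation. The list of CD4 and regulatory T cell markers, of which CD4 itself was not tested, fell as well, with a median log2 difference of −2.35. Camera gave an adjusted p = 1.10e-04, or 0.165 with an estimated correlation, and fry an adjusted p = 0.116 without the block. In it, 3 of 8 measured members fell with the block, namely CCR4, the interleukin 2 receptor chain IL2RA (10.6-fold lower) and the CD40 ligand CD40LG (5.38-fold lower), and the same number fell when adjusted over the list alone. FOXP3, the regulatory T cell factor, was at 17.9 ± 5.19 in nonbinders and 2.65 ± 4.58 in binders and did not pass (adjusted p = 0.513).

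The cytotoxic effector list rose, with 10 members higher and 3 lower in binders in 3 of 3 pairs. With the block, 6 of 17 measured members rose and 1 fell over all genes. Adjusted over the list alone, 6 rose and 1 fell without the block, and 9 and 1 with it. NKG7, a granule membrane protein, rose 2.23-fold, from 26000 ± 3387 to 57970 ± 7843. Its log2 difference was 1.16, with SE 0.072 and adjusted p = 0.0185 in limma with the block. PRF1, the pore-forming protein perforin, rose 2.16-fold with the block, from 48541 ± 9103 to 105456 ± 26087. GZMK, a granzyme of less differentiated CD8 T cells, fell 30.4-fold with the block, from 6054 ± 989 to 280 ± 280 (adjusted p = 0.0419). The median log2 difference of the list was 0.57, and camera gave an adjusted p = 5.31e-04, with an adjusted p = 0.165 with an estimated correlation. The cytokine and chemokine list rose at a median of 0.44 (camera adjusted p = 0.0450, and adjusted p = 0.429 with an estimated correlation). In it, 4 of 18 members rose with the block and also, without it, when adjusted over the list alone, namely CCL3, CCL4, CCL4L2 and the cytokine TNF (2.11-fold); with the block, 7 rose and 2 fell when adjusted over the list alone. The call of this list was lost under quantile normalization, without any single library of pairs 2 and 3, and without either of these pairs.

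NK cell genes were higher in binders at camera's preset correlation. Neither NK list passed fry without the block (adjusted p = 0.0706 for markers, 0.104 for other receptors and adaptors). On the list of NK cell markers, 2 of 12 members rose with the block (PRSS23 and the integrin ligand SPON2), 5 rose when adjusted over the list alone (7 rose and 1 fell so with the block), and the median log2 difference was 1.17 (camera adjusted p = 5.22e-05, and adjusted p = 0.165 with an estimated correlation). NCAM1, the NK cell adhesion molecule CD56, was at 16.4 ± 23.3 in nonbinders and 513 ± 348 in binders (log2 difference 5.74, SE 1.13; adjusted p = 0.141). FCER1G, a signalling adaptor of NK and myeloid cells, was at 46.9 ± 42.1 against 694 ± 680 (log2 difference 3.98; adjusted p = 0.235). Of 26 other NK receptors and adaptors, 3 rose with the block and 9 when adjusted over the list alone (16 rose and 1 fell so with the block), at a median of 0.95 (camera adjusted p = 6.03e-07, and adjusted p = 0.165 with an estimated correlation). The 3 were the Fc receptor gene FCGR3A, which rose 5.02-fold, the SLAM family receptor gene CD244 and the inhibitory receptor gene LILRB1. Of the 12 NK markers, 8 also stood on other lists. The 7 measured killer immunoglobulin-like receptor genes had a median of 1.39, with no member past the threshold over all genes, and 0 without the block but 2 with it when adjusted over the list alone (camera adjusted p = 0.0120, and adjusted p = 0.509 with an estimated correlation); these genes share reads, and the list's call was lost without nonbinder library 3 and without pair 3.

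Among the effector-lineage transcription factors, 1 of 18 rose with the block and 5 when adjusted over the list alone (6 rose and 2 fell so with the block), at a median of 0.57 (camera adjusted p = 0.00660, and adjusted p = 0.165 with an estimated correlation); the call was lost without pair 3. ZEB2, a factor of terminal effector cells, rose 1.81-fold with the block, from 30658 ± 7968 to 55048 ± 10609 (adjusted p = 0.0319), and BHLHE40 had a log2 difference of 1.11 (adjusted p = 0.0506 with the block). Trafficking receptors and integrins moved in both directions, and the list did not pass (adjusted p = 0.480): with the block, 5 of 30 members rose and 4 fell, and 8 and 9 did so when adjusted over the list alone, or 11 and 13 with the block. The integrin chain gene ITGAM rose 3.55-fold with the block, from 2555 ± 842 to 8861 ± 1470.

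**Figure D3:**
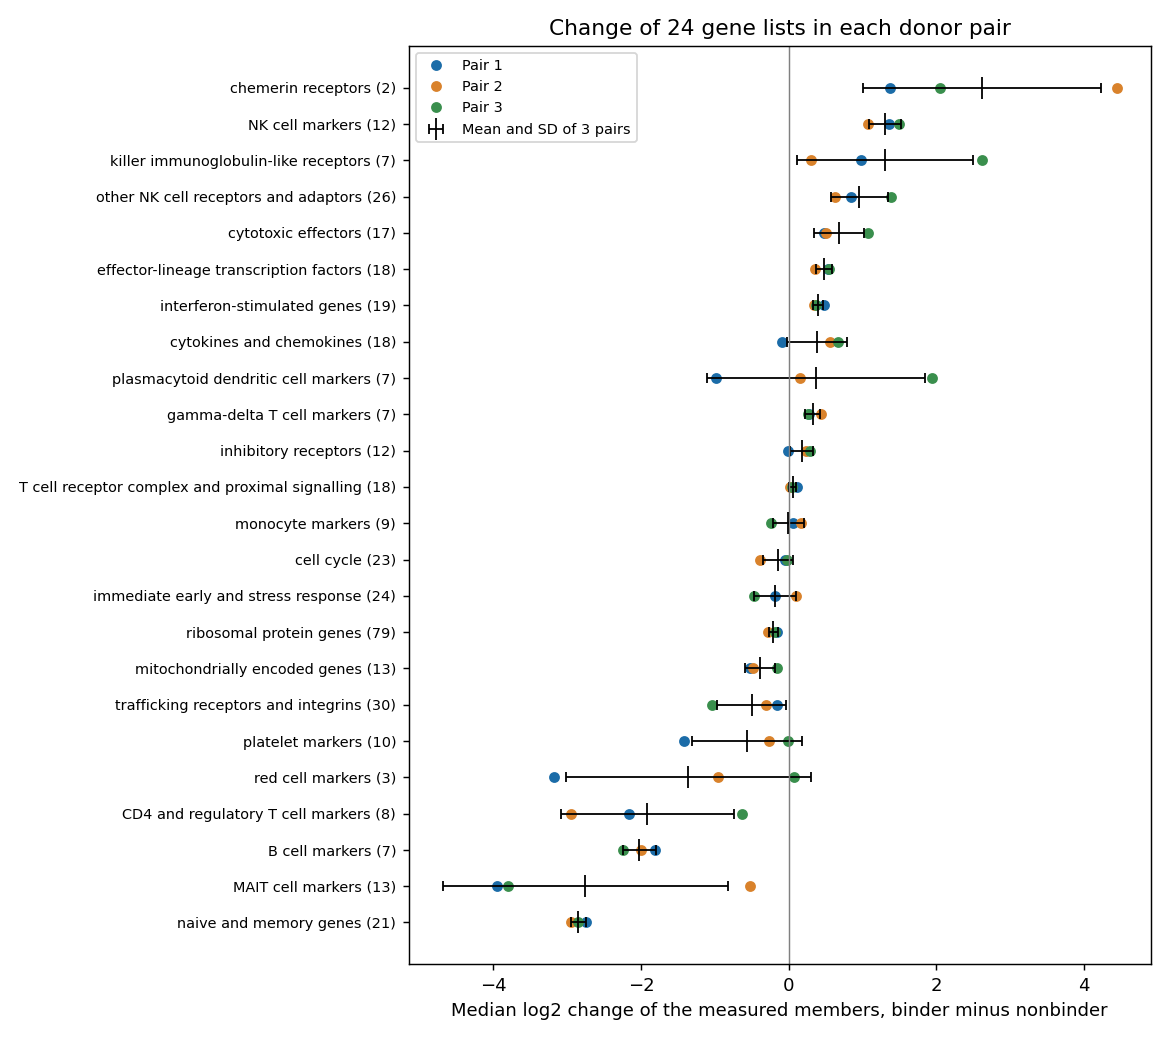
Median log2 change of the measured members of 24 gene lists, binder minus nonbinder, in each of 3 donor pairs (points), with the mean and SD over pairs (bars); the number of measured members stands in parentheses. The naive and memory list lies between −2.95 and −2.74 in the 3 pairs and the NK cell marker list at 1.07 or above.

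Genes of the T cell receptor complex did not pass as a list (18 members, median log2 difference 0.07; adjusted p = 0.534). In it, CD247, the receptor's zeta chain, rose 1.58-fold and CD5, an inhibitor of receptor signalling, fell 1.96-fold with the block, and CD3G and CD5 passed when adjusted over the list alone, where 3 members rose and 3 fell with the block. TRAC, the constant region of the receptor's alpha chain, was at 32604 ± 5691 in binders and 28352 ± 1418 in nonbinders (log2 difference 0.19; adjusted p = 0.813). Interferon-stimulated genes did not pass without the block (19 members, median 0.37; adjusted p = 0.0991) and passed with it (adjusted p = 0.0162, or adjusted p = 0.442 with an estimated correlation), with no single member past the threshold over all genes; adjusted over the list alone, none passed without the block, and 7 rose and 1 fell with it. No list passed among inhibitory receptors (12 members; adjusted p = 0.284), cell cycle genes (23 members; adjusted p = 0.549), immediate early and stress genes (24 members; adjusted p = 0.503) and gamma-delta T cell markers (7 members; adjusted p = 0.415). The same held for markers of monocytes (9 members; adjusted p = 0.684), plasmacytoid dendritic cells (7 members; adjusted p = 0.415), B cells (7 members; adjusted p = 0.173), platelets (10 members; adjusted p = 0.355) and red cells (3 members; adjusted p = 0.549). The B cell list nevertheless had a median log2 difference of −1.85, with pair medians between −2.25 and −1.81, and its member MS4A1, the B cell surface protein CD20, was at 481 ± 62.5 in nonbinders and 41.8 ± 55.4 in binders (adjusted p = 0.316). Without the block, no member of these 9 lists passed when adjusted over the list alone. With the block, the cell cycle gene TOP2A, the stress gene TNFAIP3 and the B cell gene IGHM fell over all genes. With the block and adjusted over the list alone, 2 inhibitory receptor genes and 1 gamma-delta marker rose, 1 cell cycle gene rose and 2 fell, 1 immediate early or stress gene rose and 4 fell, and 2 monocyte and 2 B cell markers fell.

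Ribosomal protein genes and mitochondrially encoded genes were slightly lower in binders. The 79 ribosomal protein genes had a median log2 difference of −0.19 (camera adjusted p = 1.26e-05, and adjusted p = 0.636 with an estimated correlation) and no member passed over all genes; adjusted over the list alone, none passed without the block and 13 fell with it. The 13 mitochondrial genes had a median of −0.38 (camera adjusted p = 0.00363, and adjusted p = 0.576 with an estimated correlation); MT-ND1, a complex I subunit, fell with the block over all genes, and adjusted over the list alone none passed without the block, while 12 fell and 1 rose with it. Both calls were lost without nonbinder library 2, and that of the mitochondrial genes also without binder library 1. Mitochondrial reads made up 1.93% ± 0.368 of binder libraries and 2.39% ± 0.294 of nonbinder libraries (SD, n = 3), and the share was lower in binders in 3 of 3 pairs. A two-sided exact permutation test that ignored the pairs gave p = 0.3, where 0.1 is the smallest it can give here. On the leading principal component, with 35.3% of the variance, nonbinder library 1 stood apart from the rest (score −145, where the others lay between −11.7 and 105).

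In the authors' deposited table, 484 genes had an adjusted p under 0.05, 149 of them higher and 335 lower in binders. Of the genes that rose with the donor as a block, 49 were also called higher in the authors' deposited table, where 0.531 would be shared by independent lists, and of those that fell 99 were also called lower, where 2.27 would be. All 3 genes called without the block were called in the authors' deposited table. CMKLR1 had a log2 fold change of −4.48, nonbinder over binder, with an adjusted p of 0.00172 in the authors' deposited table. Both sets of calls come from the same 6 libraries, so neither is independent evidence for the other. The deposited fold changes are mostly plain ratios of group means, which points to a test without a donor term. The calls with the block, compared above, come from a fit with that term.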

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

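Of 2426 values of named genes and lists under the alternatives, 2299 kept their direction and their side of the threshold, 87 came to pass it, 30 ceased to pass it and 10 turned. Only 3 genes passed as reported, so most gene values that kept their side failed in both settings. The share kept is therefore no measure of how stable the calls were. The settings that combine the block with another choice were chosen after seeing the data. The planned edgeR and DESeq2 fits on whole reads, with and without the block, were not run, because the automated check of units applied to the files takes recovered reads only for steps further from 1 than those of 3 libraries, although the values are whole multiples of these steps; depth, 45120689 to 52428780 reads, thus enters no test. Genes higher in binders numbered 63 with the replicate block, 1 with a pseudocount of 10, 1 with a minimum mean of 50, 4 with array weights and 1 with a robust variance prior, against 0 as reported. Genes lower in binders numbered 119 with the replicate block, 10 with a pseudocount of 10, 5 with a minimum mean of 50 and 18 with array weights, against 3, and between 0 and 11 when libraries or pairs were left out. Lists called numbered 0 higher and 0 lower with an estimated correlation, and 3 to 7 in each direction when libraries or pairs were left out. With the block, 100 genes were higher with a pseudocount of 10 and 95 with a minimum mean of 50; leaving out pairs gave 0 to 39 higher and 0 to 85 lower, with 0 without pair 1 or pair 2. All 182 calls with the block kept their direction in each of these settings. A call that moved 1 way in 3 of 3 pairs could not turn when a pair was left out. The other settings reuse the same libraries, so the kept directions are no independent evidence. Besides the changes named beside the results, the block changed no list's call, and scalings moved the median of all genes to at most 0.04 on the log2 scale. The CMKLR1 difference stayed between 4.20 and 7.09, with adjusted p from 0.0729 to 0.695. ALAS2 turned to −0.41 with a pseudocount of 10 and ran from −1.59 to 1.40 when libraries or pairs were left out; the ranges were −1.76 to 0.063 for ITGA2B, −3.08 to 0.033 for HBB and −1.13 to 0.046 for CCRL2. For these changes the cause was not tested, apart from the fewer samples left in.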

Other observations

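The tests of sorted-in NK or naive cells, of nonbinder library 1 and of scaling, and that of splits for single genes, were chosen after the results were seen, as were the genes named in the next sentences. The first of these genes stand outside the fixed lists and were lower in binders; no enrichment was tested for them. With the donor as a block, the chemokine gene CCL20 fell to 2 reads in binders from 529 in nonbinders (ratio of levels 270, 95% interval 74.5 to 2238), and IL23A, a subunit of interleukin 23, fell by 3.46 on the log2 scale, from 1274 ± 628 to 140 ± 99.0 normalized counts. The phosphatase gene DUSP4 fell by 3.90 on the log2 scale. TNFSF8, the CD30 ligand, fell 6.06-fold, the growth factor gene AREG 2.29-fold, the small GTPase gene GEM 15.7-fold and ZEB1, a transcriptional repressor, 4.23-fold. The related factor ZEB2 rose 1.81-fold, so that both members of this pair changed in opposite directions in 3 of 3 pairs.

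Binders held more of PLEK, a protein kinase C substrate, which rose 2.73-fold with the block from 14851 ± 4375 to 40812 ± 13495. The prostaglandin E receptor gene PTGER2 rose 2.91-fold, the soluble collagen receptor gene LAIR2 3.86-fold, the phosphatase gene PTPN6 2.20-fold and CTSD, the protease cathepsin D, 2.42-fold. The granzyme gene GZMH rose 3.00-fold, while GZMK fell by 4.93 on the log2 scale.

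Splitting the 6 libraries into 3 and 3 in other ways cannot give a share under 0.05, since there are 10 splits; the real split called 3 genes and the highest other split 0. For lists under camera's preset correlation, the real split called 11 and the highest other 7, or 6 among the splits that also part all 3 pairs. With the block there are 4 ways to exchange the labels within pairs, again too few. The real one called 182 genes and the highest other 0. In each of these 3 counts no arrangement but the real one gave as many.

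Most NK cell genes were higher in binders, NCAM1 and SH2D1B among them, with 9 of 12 markers higher and 1 lower in 3 of 3 pairs. SH2D1B rose from 96.6 ± 133 to 3550 ± 4744 normalized counts (log2 difference 6.36, limma adjusted p = 0.352). The authors' deposited table gives no adjusted p for it. Of 26 other NK receptors and adaptors, 17 were higher and 2 lower in 3 of 3 pairs. The 2 were NCR3 (2060 ± 349 in nonbinders, 1303 ± 634 in binders) and KLRC1 (1328 ± 1078 in nonbinders, 867 ± 649 in binders). The library of nonbinder 1 standing apart does not account for the higher NK cell markers. The lower median change of the NK marker list in pairs 2 and 3 was 1.07, against 1.36 in pair 1. NK cells in the binder sort cannot be told apart from NK genes expressed by the binders. The 7 T cell genes CD3D, CD3E, CD3G, TRAC, TRBC1, TRBC2 and CD8B were assumed to be lacking in NK cells, which was not measured. Their mean median change was 0.15 (SD 0.068 over pairs), so they did not fall. Their high level would still hide a small share of NK cells, which could supply SH2D1B and NCAM1. The CD8 gate would remove NK cells that lack CD8, and how many others it let through was not measured. That the binders themselves express these genes, as late effector CD8 T cells may, is a hypothesis that remains open.

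Naive and memory genes were lower in binders, and CCR7 was at 12342 ± 5291 normalized counts in nonbinders although the gate excluded cells with the protein. A scaling difference does not account for this, since after quantile normalization the mean over pairs of the list's median was −2.85 (SD 0.14). Naive cells carried into the nonbinder sort cannot be told apart from lower expression in the binders, since the list without CCR7 moved by −2.58 (SD 0.078) and a carried-over naive cell would bring all of these genes. Markers of B cells, which the CD8 gate selects against, had lower values in binders (pair medians between −2.25 and −1.81), without passing as a list (adjusted p = 0.173). That nonbinding cells within the shared EMRA gate are less differentiated is a hypothesis, and it was not tested.

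Of 13 MAIT cell markers, 10 were lower and 2 higher in binders in 3 of 3 pairs. The median change of the list was only −0.52 in pair 2. Of the 17568 genes tested, 3610 were lower and 3631 higher in 3 of 3 pairs. With the block 4 of the markers fell, CXCR6 and CCR6 among them. Naive cells carried into the nonbinder sort would not account for these 4 if naive cells lack them, which was assumed and not measured. MAIT or other memory-type cells among the nonbinders may explain the lower markers, although the CD45RO-negative gate selects against cells that carry this protein. This and expression by the EMRA cells themselves remain open, and 5 of the 13 markers stand on other lists.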
